A study of Mus musculus with 21 samples.

How the data were processed

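Messenger RNA was measured in pancreatic tumours of mice that carry an oncogenic Kras allele switched on in the pancreas by Ptf1a-driven Cre. The animals had been irradiated and had received bone marrow with floxed Rc3h1 and Rc3h2, the genes of the RNA-binding proteins Roquin-1 and Roquin-2. In 1 group the marrow also carried a Cd4-driven Cre, so that both genes are deleted in T cells (DKOT marrow), and in the other group it did not (WT marrow). Pieces of tumour tissue and cell lines grown from the tumours were sequenced. Per the labels' protocols, cultures were passaged until stromal cells were no longer seen and poly(A) RNA was primed with barcoded oligo-dT primers that hold unique molecular identifiers. The amplified fragments came from the 3′ ends of transcripts.

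The values used are the whole-number counts per gene and well that the authors deposited, with no normalization. The submitters' processing notes name the mouse build GRCm38 and DESeq2, with no version or role. The aligner, the annotation and how the molecular identifiers were collapsed are not given in the sources used here, so reads shared between close relatives (trypsins, kallikreins, Reg genes, amylases and MHC class I genes) may have been split or lost, and values of such genes are uncertain. Strand use in counting is likewise not given. The table held 31500 genes and 40 columns, and all 40 columns were mapped to samples by matching the names in the deposited well annotation to the titles. Each of the 20 libraries had 2 technical runs (separate wells), which were summed and counted as 1 sample. Another 1 of the 21 samples in the labels holds reads with unassigned barcodes and was not analysed here.

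The 20 libraries came from 12 mice, and 7 of these gave both tissue and a line. Mice are named by the labels' codes, W for WT and D for DKOT marrow. Lines A and B both came from mouse D13 and were summed, so that the mouse was the replicate, which left 19 units. Total counts ranged from 383733 to 2765826 in WT tissue, from 2110421 to 2823031 in DKOT tissue, from 1379577 to 2588509 in WT lines and from 2106795 to 2579898 in DKOT lines. The shallowest tissue library was W11. Run 1 of line G, from mouse W12, held 66538 counts against 1313039 in run 2. Upper limits for genes without counts stand for 3 counts in the group's total and cover counting error only.

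Genes were filtered with filterByExpr by group (minimum count 10), scaled by the trimmed mean of M values (TMM) and tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Tissue and lines were compared between marrow groups in separate fits. The difference of the marrow effect between lines and tissue, and lines against tissue, were tested in 1 fit of all 4 groups. The labels give no day or plate batch that could be set against the groups. Low levels of the Y-linked Ddx3y occurred only in tissue with DKOT marrow, so Y-linked level and marrow group are partly confounded there. Before the data were examined, 48 gene lists were fixed (805 genes, of which 13 were missing from the table), covering immune, stromal, endocrine and epithelial cell types, signalling responses, metabolism and tissues that could contaminate a dissection. Sex-linked genes were 1 of these lists and were used only as a check and as a covariate. Lists with at least 3 tested genes were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over lists, and again with an estimated correlation. Each list is also given by how many members passed over all genes and how many when adjusted over the list alone. Scores of lists are means of log2 CPM (counts scaled to the library total) with a prior count of 2, and were compared by two-sided exact permutation tests. Gene levels are CPM on TMM-scaled library sizes, with SD over mice, unless they are called plain CPM.

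The genes named were set by a rule fixed before the data were examined. For tissue and for lines it takes up to 12 genes per direction with the smallest p among those past the threshold with an absolute log2 fold change of at least 1, leaving out sex-linked genes and genes without a proper symbol. Where fewer than 5 passed in a direction, the 5 with the smallest p are named as not passing. Lines against tissue take 8 per direction and the difference of effects takes 5. From each list described, up to 4 members with the smallest p are named, and Rc3h1, Rc3h2, Kras, Ptf1a and a set of cytokines are always given. Other genes are said to have been chosen after their values were seen.

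The main edgeR fits, the DESeq2 and voom fits and the camera test were run on simulated counts drawn from the real means and library sizes. The background subtraction, the splits of samples, the permutation tests and the comparisons of runs were not tested in this way. At a 2-fold change edgeR recovered 54.8% of changed genes in the tissue design, 4.2% in the line design, 5.1% for the difference of effects and 69.1% for lines against tissue. At 4-fold the shares were 92.8%, 73.9%, 52.6% and 94.8%. Of 144 edgeR calls in the tissue simulation 3 were false. DESeq2 made 23 false of 176 calls in the tissue, 21 of 131 in the line and 16 of 98 in the difference simulation. For lines against tissue its false calls were 24 of 191, against 11 of 170 with edgeR. Genes that passed with DESeq2 but not with edgeR are therefore less certain.

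Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 test, no filter and a stricter filter (mean of 10 counts), limma voom with quality weights, 1 fit of all groups, Y-linked and acinar scores as covariates, the D13 lines kept apart or used singly, replicate blocks, and leaving out each mouse in turn. Chosen after seeing the data were either run alone, run 1 of line G left out, tissue W11 and D12 left out together, the acinar list left out before scaling, and subtraction of a background shared by all wells. For the last, the summed counts of all wells served as the background profile. Its amount per line well was taken from 58 marker genes of cell types that the cultures should lack, 25 of them acinar genes. The same number of counts was assumed in tissue wells.

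Tissue and line of 1 mouse are paired by the design. Over the 7 such mice the deviations from the group means correlated at −0.098 to 0.179 across genes. Gene positions are those of the GENCODE M21 annotation of GRCm38, the build the submitters name, where 117 of 118 genes looked up had a single entry.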

Results

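The series holds 3′ RNA counts from 6 tumours of mice with WT marrow and 6 of mice with DKOT marrow, from lines of 3 mice with WT marrow, and from 5 lines of 4 mice with DKOT marrow. By its title it asks how T cells that lack Roquin act on pancreatitis and pancreatic tumours through interleukin-17 and other cytokines. Libraries held 1379577 to 2823031 counts, except tissue W11 with 383733. The 2 runs of a library correlated at 0.949 to 0.977 across genes, except in tissue W11 (0.744) and line G (0.62).

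The targeted genes were measured first. In tissue Rc3h1 (chromosome 1, 160906418 to 160974978) stood at 58.5 ± 11.2 CPM with WT marrow and 49.4 ± 15.7 with DKOT marrow (SD, n = 6 each), a log2 fold change of −0.24 (SE 0.22, adjusted p = 0.773). Rc3h2 (chromosome 2, 37370069 to 37422903) stood at 45.7 ± 11.5 and 49.6 ± 13.2 CPM, a log2 fold change of 0.07 (adjusted p = 0.970). In plain CPM, single tissue libraries ranged from 25.7 to 79.9 for Rc3h1 and from 20.9 to 72.7 for Rc3h2, and lines from 21.5 to 33.3 and from 15.7 to 30.8. These levels check no label, because the deletion is limited to T cells of the marrow and a 3′ tag can lie outside the deleted part.

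Tumour tissue under DKOT marrow held far less acinar RNA, the transcripts of the digestive enzymes of the exocrine pancreas. Of 31 acinar list genes tested 29 fell, with a median log2 fold change of −4.71, and all 31 passed when adjusted over the list alone (camera adjusted p = 5.17e-118, and adjusted p = 0.0212 with an estimated correlation). The pancreatic lipase Pnlip fell from 2368 ± 2770 to 44.5 ± 14.6 CPM, a log2 fold change of −5.73 (SE 0.75, adjusted p = 0.0016, n = 6 each). The procarboxypeptidase Cpb1 (chromosome 3, 20248264 to 20275733) fell from 8058 ± 7740 to 232 ± 122 CPM, 34.7-fold, and the colipase Clps fell 37.4-fold. Among enzymes with close relatives, whose values are uncertain, the trypsin genes Prss1 and Try4 (chromosome 6, 41302269 to 41305532) had log2 fold changes of −5.68 and −5.28, the kallikreins Klk1 and Klk1b5 of −4.97 and −5.58, and the elastase Cela3b of −5.08. The protease Ctrl, the pancreatic disulfide isomerase Pdia2, the zymogen granule protein Zg16 and the serpin Serpini2 completed the 12 genes lower by the smallest p, at −5.30, −5.32, −5.04 and −5.73. Ptf1a, the transcription factor of acinar identity, had a log2 fold change of −2.91 and did not pass (adjusted p = 0.133), though it did without W13 (adjusted p = 0.014), with DESeq2 (0.0119) and with no filter (0.0328).

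The acinar list took 12.85% ± 8.997 of all counts in WT tissue and 1.03% ± 0.723 in DKOT tissue (SD, n = 6 each). Its mean log2 CPM lay below the lowest WT library in 6 of 6 DKOT libraries (difference −3.77, two-sided exact permutation p = 0.00216, the smallest that 924 splits can give). In the cell lines the list took 0.567% and 0.612% of counts. Cpb1 stood there at 205 ± 18.99 and 237 ± 29.4 CPM, close to its level in DKOT tissue. Line wells held a background in proportion to all wells together (a median of 11.85% of a well), and acinar genes lay there at 0.114 of their level in all wells, against 0.122 for islet and 0.125 for macrophage genes. The line levels are therefore at background, and the tissue fold changes are limited by it if as much reached tissue wells. With this background subtracted, an alternative chosen after seeing the data, the list median was −5.97 and Cpb1 and Pnlip were at −7.12 and −10.38, while Clps and Cela3b, at −7.28 and −6.90 with larger SEs, no longer passed (adjusted p = 0.0562 and 0.0568).

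Fewer transcripts were higher under DKOT marrow. The C-type lectin receptor Clec1b (chromosome 6, 129397297 to 129409335), which platelets carry, rose from 4.29 ± 1.91 to 26.3 ± 15.6 CPM, a log2 fold change of 2.54 (SE 0.41, adjusted p = 0.00618, n = 6 each). The G protein subunit Gnaz rose by 1.59, the neutrophil collagenase Mmp8 (chromosome 9, 7558456 to 7568485) by 1.87, Wfdc21 (chromosome 11, 83746940 to 83752642) by 3.25 and the MHC class I gene H2-Q10, uncertain because of its relatives, by 2.41 on the log2 scale. Wfdc21 varied widely among DKOT libraries (106.5 ± 107 CPM). Tnfaip2 and Cirbp, chosen after their values were seen, rose by 0.75 and 0.91. Clec1b passed whichever library was left out (adjusted p from 0.00336 to 0.0255). Gnaz no longer passed without W12 or W15 (highest adjusted p = 0.0526). Mmp8 no longer passed without any library other than W10, D12 or D15 (highest adjusted p = 0.111), and Wfdc21 and H2-Q10 without any other than D12, D14 or D15 (highest 0.148 and 0.129). With a Y-linked score as covariate Gnaz, Mmp8, Wfdc21 and H2-Q10 did not pass (adjusted p = 0.0749, 0.141, 0.111 and 0.132). Nor did Gnaz with no filter (0.0645), Mmp8 with run 2 only (0.197) or the background subtracted (0.0586, at 2.02), Wfdc21 with voom (0.0844), H2-Q10 without W11 and D12 (0.0577), or Mmp8, Wfdc21 and H2-Q10 with the acinar list left out (0.0543, 0.0632 and 0.0639).

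Neutrophil transcripts were higher as a group. All 12 tested list genes had positive log2 fold changes (median 1.41), Mmp8 alone passed over all genes, and 10 passed when adjusted over the list alone. The list was called higher (camera adjusted p = 5.46e-12), though not with an estimated correlation (adjusted p = 0.237) or the acinar covariate, where its direction turned (median −0.33, adjusted p = 0.345). The alarmin subunits S100a8 and S100a9 had log2 fold changes of 2.44 and 2.34 and the chemokine receptor Cxcr2 of 1.95, each short of the threshold (adjusted p = 0.0667, 0.102 and 0.0803). S100a8 passed without D12, D13 or D15 (lowest adjusted p = 0.0295), S100a9 without D12 or D13 (lowest 0.0315) and Cxcr2 without D12, D14 or D16 (lowest 0.0376). All 3 passed with no filter and with 1 fit of all groups, S100a8 and Cxcr2 with DESeq2, S100a8 and S100a9 with voom, the background subtracted or W11 and D12 left out, and S100a8 with run 2 only (adjusted p = 0.00328 to 0.0493). The mean log2 CPM of the list was above the highest WT library in 6 of 6 DKOT libraries (difference 1.55, two-sided exact permutation p = 0.00216).

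The list of interleukin-17 response genes moved in both directions. It shares S100a8, S100a9 and Mmp9 with the neutrophil list, and S100a8 was its highest member, so it is not independent of that list. Its median log2 fold change was 0.73, with 20 of 28 members positive, and adjusted over the list alone 11 members were higher and 3 lower. The 3 that passed over all genes were the antimicrobial lectins Reg3a, Reg3g and Reg3b, which fell by 4.96, 3.53 and 3.30 on the log2 scale. The list was called higher (camera adjusted p = 0.0206), but not with an estimated correlation (adjusted p = 0.536) or without W10 or W13 (adjusted p = 0.0995 and 0.0876). Its call was also lost with the Y-linked covariate (adjusted p = 0.414), the acinar covariate (0.362), run 1 only (0.072) and the background subtracted (0.0502). The list of interleukin-22 and STAT3 responses was called lower (camera adjusted p = 0.00916, and adjusted p = 0.335 with an estimated correlation). Of its 19 tested members 5 fell, all Reg genes (Reg3a, Reg3g, Reg3b, Reg2 by 4.06 and Reg1 by 3.01). Adjusted over the list alone, 2 were higher and 5 lower. It was not called without D17 (adjusted p = 0.0556), and with the acinar covariate its direction turned and it was called higher (median 0.43, adjusted p = 0.0152). Reg genes are made by stressed acinar cells and resemble each other, so their values are uncertain. With the background subtracted Reg3a, Reg3g, Reg3b, Reg2 and Reg1 did not pass (adjusted p = 0.0645, 0.0945, 0.116, 0.174 and 0.116), though their log2 fold changes and SEs grew, to −6.52, −4.08, −3.83, −4.88 and −3.48 with SEs of 0.879 to 1.484, from main SEs of 0.594 to 0.784, and with the Y-linked covariate Reg3a alone of them did (0.0309, the others at 0.0607 to 0.103). Reg3a and Reg2 passed whichever library was left out, while Reg3b and Reg1 did not pass without W12, W14, W15, D13, D14, D16 or D17, nor Reg3g without W12, W14, W15, D13, D16 or D17 (highest adjusted p = 0.094, 0.0848 and 0.0927).

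Most cytokine transcripts had few counts in tissue. Summed over 6 libraries, Il17a had 1 count with WT and 13 with DKOT marrow, the latter in 3 libraries with a highest value of 3.68 plain CPM in D13. These were too few to pass the filter on low counts. Il22 had 2 counts and 0 (a limit of 0.198 plain CPM in DKOT tissue), Il21 0 and 3 (a limit of 0.248 in WT tissue), Ifng 2 and 6, Il4 1 and 2, Il13 1 and 3, and Il10 7 and 8. Il5 had no count in either group, and Il17f was not in the table. At this depth these cytokines were not compared in the main test, which gives no result for them. Tnf, at 31 and 69 counts, had a log2 fold change of 0.55 (SE 0.40, adjusted p = 0.692), and Il6, at 70 and 81 counts, of −0.40 (SE 0.44, adjusted p = 0.823), and neither passed. The T cell list was not called (camera adjusted p = 0.889), with a median log2 fold change of 0.45 and 0 of 16 tested members past the threshold, also when adjusted over the list alone. Its median and mean (0.22) are positive and its camera direction is down, and Trbc1, Trbc2 and Thy1 had log2 fold changes of 0.71, 0.66 and 0.50 and the interleukin-7 receptor Il7r of −1.01. Trbc2 was at −0.31 without D12. The T cell list score was 5.669 in D12, against 2.319 to 3.6 in the other DKOT and 2.663 to 4.027 in the WT tissue libraries. Kras, at 0.09, did not pass (adjusted p = 0.959).

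Genes of the unfolded protein response, which is strong in secretory cells, were lower as a group (median log2 fold change −0.38, camera adjusted p = 1.92e-09, and adjusted p = 0.239 with an estimated correlation). Creld2 fell by 0.95 and Herpud1 by 1.22, and 8 of 19 members were lower when adjusted over the list alone. Manf and Hspa5, at −0.68 and −0.62, did not pass, and Manf did without W13 (adjusted p = 0.038), with DESeq2 (0.00941) and with 1 fit of all groups (0.0379), and both did with voom (0.0471 and 0.0382). Herpud1 did not pass without any 1 of W10, W14, W15 or D13 to D17 (highest adjusted p = 0.134). Neither Creld2 nor Herpud1 passed with the background subtracted (log2 fold changes −1.03 and −1.36, adjusted p = 0.11 and 0.159) or the Y-linked covariate (0.0529 and 0.189), nor Herpud1 with run 1 only, 1 fit of all groups or the acinar list left out (0.0814, 0.119 and 0.0671). With the acinar covariate the list turned and was not called (median 0.16, adjusted p = 0.0898).

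Type I interferon response genes were called lower (camera adjusted p = 3.25e-06, and adjusted p = 0.536 with an estimated correlation), with a median log2 fold change of −0.43 and 0 of 19 members past the threshold, or 1 when adjusted over the list alone. Oas1a, Rsad2, Oas2 and Mx1 were at −0.88, −0.89, −1.22 and −0.96, of which Oas1a and Rsad2 passed with voom (adjusted p = 0.0498 and 0.0447). Islet hormone and secretory genes were called lower (median −0.68, 14 of 14 negative, 0 passing and 0 when adjusted over the list alone, camera adjusted p = 1.12e-05, and adjusted p = 0.536 with an estimated correlation), with Ttr, Sst, Ins2 and G6pc2 at −1.13, −1.29, −1.50 and −1.16. With the acinar covariate the islet list turned and was called higher (median 1.30, adjusted p = 0.0055). Ttr passed without D14 (adjusted p = 0.0342). Gastric and mucinous genes were called lower (median −0.54, camera adjusted p = 0.00102, and adjusted p = 0.614 with an estimated correlation), but not without D12 (adjusted p = 0.08) or with the acinar covariate (0.14). Of these the mucin-like glycoprotein Dmbt1 fell by 2.95, the only one of 20 past the threshold and when adjusted over the list alone, and Tff2, Gkn3 and Tff1 were at −1.19, −1.44 and −1.18. Dmbt1 did not pass without W12, W14, D13, D16 or D17 (highest adjusted p = 0.0761) or with the background subtracted (log2 fold change −3.51, adjusted p = 0.083), and Gkn3 passed without D14 (adjusted p = 0.024).

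Endothelial genes were called higher (median log2 fold change 0.43, 19 of 19 positive, 0 passing and 0 when adjusted over the list alone, camera adjusted p = 0.000159, and adjusted p = 0.536 with an estimated correlation). Cldn5, Flt4, Emcn and Eng were at 2.10, 1.25, 0.55 and 0.43, Cldn5 passed with DESeq2 (adjusted p = 0.0426), and the list was not called without D12 (adjusted p = 0.0624), with voom (0.383) or with the acinar covariate, where it turned (median −0.29, adjusted p = 0.123). Known Roquin target mRNAs were called higher (median 0.36, 12 of 16 positive, 0 passing and 0 when adjusted over the list alone, camera adjusted p = 0.0177, and adjusted p = 0.335 with an estimated correlation). Zc3h12a, Id1, Id3 and Tnfrsf9 were at 0.90, 0.44, 0.44 and 1.20, and the call was lost without W11, W12, D12, D15 or D17 (highest adjusted p = 0.115), with voom (0.0527), with the background subtracted (0.0634) and with the acinar covariate (0.735). It was also lost with W11 and D12 left out together (0.181) and with the replicate block on shared numbers (0.266), in all in 10 of 25 alternatives. The deletion is limited to T cells while these are whole tumour pieces, so the call does not show a change within T cells. Zc3h12a is also in the interleukin-17 response list, and Id1 and Id3 are in that of TGF-β targets.

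In total 91 of 11976 genes passed between tissue groups, 7 higher and 84 lower (edgeR quasi-likelihood test), of which 5 and 81 changed at least 2-fold. At an unadjusted 0.05 there were 1146 genes, with 599 expected by chance. The acinar list held 29 of the 84 lower genes. Of 44 lists 15 were called, 7 higher and 8 lower, and the acinar list alone was called with an estimated correlation. Without D12, whose library held 558 plain CPM of the fat cell hormone Adipoq against at most 14.3 in other tissue (chosen after its values were seen), 246 genes passed, 66 higher and 180 lower, and without W11 and D12 187 passed, 47 higher and 140 lower. With the acinar score as a covariate 0 passed in edgeR (212 at an unadjusted 0.05, not run with DESeq2 or voom), and Cpb1 moved from −5.12 (SE 0.67) to −0.28 (SE 0.38), while Prss1 stayed at −4.78 (SE 1.10, from −5.68, SE 0.63) and Gnaz at 2.07 (SE 0.67, from 1.59, SE 0.29), the scores of the groups not overlapping. The acinar list was then at a median of 0.24 and not called (adjusted p = 0.234).

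**Figure D1:**
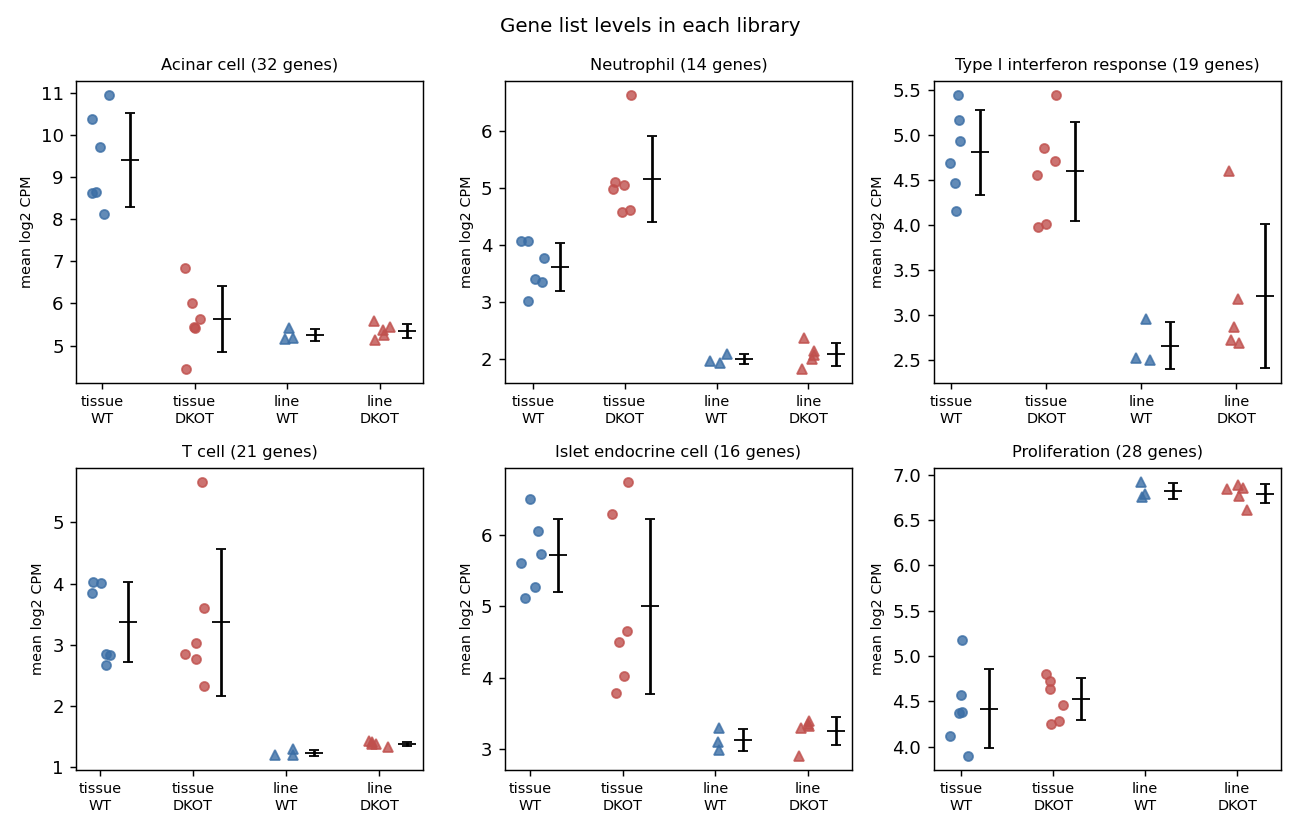
Mean log2 CPM of 6 gene lists in each of the 20 libraries (y axis), by group (x axis), with 1 point per library, circles for tissue and triangles for lines, and black bars for the mean and SD. Acinar levels of the 6 DKOT tissue libraries lie below all 6 WT tissue libraries, neutrophil levels lie above them, and proliferation is higher in the 8 lines than in the 12 tissue libraries.

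Lines grown from the tumours were compared to see whether the marrow group left a difference in the cultured cells. No single gene differed between lines of mice with DKOT and WT marrow (0 of 11056 by edgeR, DESeq2 or voom, smallest adjusted p = 0.9999, n = 4 DKOT and 3 WT mice). At an unadjusted 0.05 there were 179 genes, with 553 expected by chance, 148 with DESeq2 and 213 with voom. The 5 genes with the smallest p on the higher side, none passing, were the apoptosis repressor Nol3 (chromosome 8, 105276140 to 105281939), mt-Nd6, Esco2, Psme1 and Cyb5rl, at log2 fold changes of 2.52, 0.76, 0.58, 0.60 and 1.03. On the lower side they were Gpm6b, Gpx2, Gtf2ird2, Chchd6 and Abl1, at −0.80, −2.34, −1.19, −0.63 and −0.61. With 3 and 4 mice, changes of 2-fold would mostly be missed, as the simulated recovery of 4.2% shows.

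Interferon genes were the group that stood out in the lines. The interferon-γ response list was called higher (median log2 fold change 0.58, 17 of 18 positive, 0 passing and 0 when adjusted over the list alone, camera adjusted p = 1.44e-06), but not with an estimated correlation (adjusted p = 0.578). H2-D1, an MHC class I gene with close relatives, Psmb8, Gbp7 and Psmb9 were at 0.76, 0.77, 0.67 and 1.12. Type I interferon genes were called higher as well (median 0.997, 13 of 14 positive, 0 passing and 0 when adjusted over the list alone, camera adjusted p = 1.44e-06, and adjusted p = 0.879 with an estimated correlation). Ifih1, Irf9, Ifit3 and Isg15 were at 1.05, 0.99, 0.93 and 1.89. The line of D17 held 133.7 plain CPM of Isg15 against 6.65 to 22.9 in the other 7 lines, and without D17 the type I list was not called (median 0.21, adjusted p = 0.0898). Genes of cholesterol and fatty acid synthesis were called higher (median 0.17, 20 of 20 positive, 0 passing and 0 when adjusted over the list alone, camera adjusted p = 0.0386, and adjusted p = 0.879 with an estimated correlation), with Fdft1, Fdps, Scd1 and Srebf2 at 0.38, 0.27, 0.38 and 0.21. That call was lost without W11, W12, D15 or D17 (adjusted p = 0.0705, 0.864, 0.158 and 0.192), and its median without W12 was −0.06. It was also lost with no filter, either run alone, 1 fit of all groups, voom, the Y-linked covariate or the D13 lines kept apart (adjusted p = 0.055 to 0.381). With run 1 of each library alone the interferon-γ and type I lists were not called (adjusted p = 0.998 and 0.489). In that fit W12 stood on run 1 of line G alone, with 66538 counts and an estimated 89.74% background. Both lists were called with run 2 alone and with that well left out, but each of these fits called 13 lists, all higher. In run 2 the estimated background was 12.04% to 18.56% in DKOT line wells and 10.04% to 10.61% in WT line wells. Background thus differed with the marrow group in that run, so these 2 fits are weak support for the calls. With the background subtracted the same 3 lists were called as in the main fit. In the main fit the other 38 of 41 lists were not called. Leaving out lines changed the number of lists called to 9 without W11, 10 without W12, 6 without W15 and 7 without D17.

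The contrast of the marrow effect in lines minus that in tissue passed for 21 of 13301 genes, all higher (708 at an unadjusted 0.05). Most of these genes encode acinar enzymes. Try4, Cpb1, Cela3b, Klk1 and Ctrl differed by 5.37, 5.31, 5.24, 4.98 and 5.16 on the log2 scale (each adjusted p = 0.0244), and 16 of the 21 were acinar list genes. The other 5, chosen after their values were seen except Klk1, were Klk1, Pdia2, Reg3d, 2210010C04Rik and 1810028F09Rik. Cadm4, Gnpda2, Mtss2, Gpm6b and Htatip2, with the smallest p on the lower side, were at −1.80, −1.04, −2.29, −1.44 and −0.72 and did not pass (adjusted p = 0.269 to 0.422). In the lines Try4 stood at 142 ± 11.8 and 152 ± 23.8 CPM (n = 3 and 4), and acinar genes there were at the background level given above, so a marrow effect on them in lines could not be measured and the contrast restates their fall in tissue. Of 46 lists 8 were called for this contrast, 6 higher and 2 lower, and the acinar list alone with an estimated correlation (adjusted p = 0.0133). Type I interferon genes were called higher (median 1.51, 19 of 19 positive, 0 passing, camera adjusted p = 4.33e-11, and adjusted p = 0.3375 with an estimated correlation). Their medians were −0.43 in tissue and 0.997 in lines, where the call was lost without D17. With the mouse as a block 42 genes passed. No gene passed with the background subtracted (572 at an unadjusted 0.05) or without the lines of W11, W12, W15 or D15 (767, 670, 748 and 696), 12 passed without D13, and 11 each without D16 and D17. Acinar genes were 25 of the 58 markers that set the background, so its subtraction removes most acinar counts from line wells by construction.

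Against tissue, lines gained transcripts of cell division and lost those of immune and stromal cells. The recombinase Rad51 (chromosome 2, 119112793 to 119147445) rose 7.25-fold, Ccnb1, which drives entry into mitosis, 7.90-fold, and the mitotic activator Cdc20 10.3-fold. Rad51 went from 10.9 ± 1.69 and 9.23 ± 2.09 CPM in tissue to 73.8 ± 3.35 and 70.6 ± 11.4 CPM in lines (WT and DKOT, adjusted p = 8.52e-12). Cenph, Orc6, Dtymk, Gar1 and Rrp1 rose by 3.22, 2.07, 2.00, 2.12 and 2.00 on the log2 scale. The macrophage receptor Csf1r (chromosome 18, 61100598 to 61132149) fell 7.88-fold, the complement subunit C1qa 11.6-fold and the lysosomal protease Ctss 13.1-fold. Laptm5, Spon1, Lcp1, Cybb and Cd84 fell by 3.67, 3.14, 3.54, 3.41 and 3.78. Macrophage genes in line wells were at the background level given above, which limits the size of such falls. Among the alternatives Csf1r, C1qa and Ctss reached log2 fold changes of −4.536, −8.581 and −12.775. Laptm5, Spon1, Lcp1, Cybb and Cd84 reached −7.671, −4.998, −7.632, −6.661 and −7.133.

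By group, 28 of 28 proliferation genes rose (median log2 fold change 2.35, Aurka 3.50, Mcm7 2.10, Ccnb2 2.45, camera adjusted p = 2.84e-31, and adjusted p = 0.0679 with an estimated correlation). Of 20 macrophage genes 19 fell (median −3.54, Itgam −3.98, C1qb −3.38, camera adjusted p = 1.96e-20, and adjusted p = 0.0584 with an estimated correlation). Of 26 fibroblast and matrix genes 25 fell (median −3.10, Thy1 −3.18, Col3a1 −3.42, Mfap5 −3.28, Col1a2 −3.30, camera adjusted p = 2.61e-13, and adjusted p = 0.0751 with an estimated correlation). Among the alternatives Thy1, Col3a1, Mfap5 and Col1a2 reached −5.031, −6.391, −5.555 and −5.995, so the sizes of these falls are uncertain. Targets of RAS and ERK signalling were called higher (camera adjusted p = 0.0304, and adjusted p = 0.596 with an estimated correlation), with 13 of 24 up and 4 down. Among them Fosl1, Myc, Dusp4 and Ccnd1 rose by 3.03, 2.03, 2.09 and 1.81, and the call was lost without the D17 line (adjusted p = 0.0539). Ductal genes were not called as a list (camera adjusted p = 0.941), and their median and mean differ in sign (0.09 and −0.17). Of 20 ductal genes 8 rose, among them Krt18 and Anxa2 by 1.24 and 0.99, and 6 fell, among them Onecut1 and Cftr by 3.28 and 3.34. In each of these lists the counts were the same when adjusted over the list alone.

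In total 9235 of 13301 genes passed, 4441 higher and 4794 lower, and 25 of 46 lists were called, 4 higher and 21 lower, of which 0 were called with an estimated correlation (Proliferation and Macrophage lists came closest). Every line well also held transcripts of cell types it should lack, in proportion to their level in all wells together. With this background subtracted the macrophage median was −6.47 and the proliferation median 2.86.

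**Figure D2:**
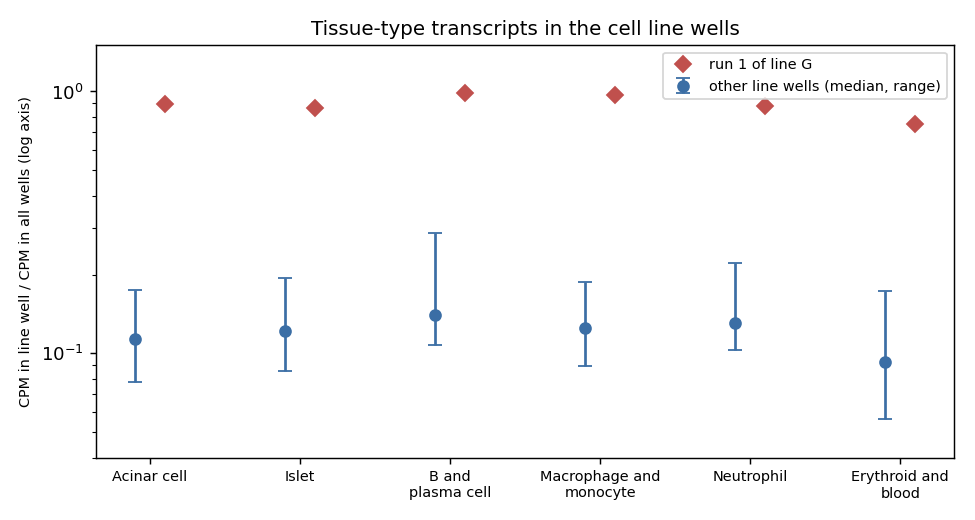
CPM of 6 marker lists in the cell line wells, divided by their CPM in all wells together (y axis, log scale), for 15 line wells as median and range (circles, bars) and for run 1 of line G (diamonds). Medians lie between 0.0924 and 0.14 in all 6 lists, and run 1 of line G lies between 0.75 and 0.989.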

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

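The counts over other splits of the samples and the test of the difference between lines and tissue were planned, and all other tests in this part were chosen after the result was seen. A sample far from the rest of its group was found in 14 of 168 pairs of a group and a result, where chance gives about 1 in 20. The values below are the gap from that sample to its nearest neighbour, divided by the range of the group.

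In DKOT tissue, library D13 was highest in S100a8 (0.632), S100a9 (0.718) and the neutrophil list (0.744), and lowest in Pnlip (0.75). D12 was highest in Trbc1 (0.671) and Creld2 (0.913). In WT tissue, W11, the library with the fewest counts, was lowest in Eng (0.671), Il6 (0.712) and the unfolded protein response list (0.645). Among DKOT lines D16 was highest in Nol3 (0.83), and D17 was highest in Fdft1 (0.842) and Fdps (0.884) and lowest in Scd1 (0.837). Total counts were highest for D13 (0.833), where 2 lines had been summed. The contrast of the marrow effect in lines minus that in tissue was 5.373, 5.315, 5.235, 4.981 and 5.16 on the log2 scale for Try4, Cpb1, Cela3b, Klk1 and Ctrl in the test of the difference itself, but acinar genes in lines were at the level of the background shared between wells, so it restates their fall in tissue.

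Acinar transcripts were lower in DKOT tissue. A few genes taking most of the counts is excluded as the cause, since counts outside the acinar list and the Reg genes shifted by 0.246 on the log2 scale against a median of −4.71. RNA from other wells, if it had the profile seen in line wells, is excluded as the whole cause, because in any amount it moves a well towards the acinar share of all wells together (4.03%) and not past it, and 11 of 12 tissue libraries lay beyond that share by more than the 1.51-fold spread of that profile (5 of 6 WT above, 6 of 6 DKOT below). A smaller share of normal pancreas in the DKOT pieces is not excluded. Acinar fell more than islet transcripts (acinar minus islet score −3.014, two-sided exact permutation p = 0.00216, the smallest possible). However, islet scores had less room to fall to the level of the lines (2.91 to 3.403). They also lay below the lowest WT library in 4 of 6 DKOT libraries. In D14 and D15 islet scores (6.743 and 6.292) were not below the WT range (5.115 to 6.496), while acinar scores were. A loss of acinar cells or of their enzyme transcripts that goes with the marrow group stays open as a hypothesis, as does a difference in where pieces were taken.

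Neutrophil transcripts were higher in DKOT tissue. D13 alone is excluded as the cause, since the score differed by 1.255 without it (two-sided exact permutation p = 0.00216 over 462 splits). More blood in the pieces cannot be told apart from more neutrophils in the tumour, because the neutrophil minus erythroid score differed by 1.018 with a two-sided exact permutation p = 0.186, and erythroid scores varied widely. An effect of the marrow group stays open as a hypothesis.

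Transcripts of tissue cell types appeared in every line library, and their ratio to the level in all wells together differed by at most 1.51-fold among 6 unrelated lists, as a background shared between wells would give. Tissue cells left in the cultures are excluded as the whole cause, provided that the 2 wells of a library, which the labels call technical replicates, held the same RNA, since in 7 of 8 lines the share of these transcripts differed between wells beyond counting error and, in the same 7, lay outside the central 95% of 1000 random sets of line genes of matched level. The ratio of run 2 to run 1 was 2.096 in line A, 1.378 in B, 1.032 in C (the exception), 1.324 in D, 1.232 in E, 0.9046 in F, 0.1151 in G and 0.9295 in H, and the central ranges of the random sets lay within 0.94 to 1.068 outside line G. The background made up a median of 11.85% of a line well (8.82% to 18.56%) and 89.74% of run 1 of line G. The same number of counts would be 70.37% and 72.91% of the W11 tissue wells and 11.18% of other tissue wells, if as much reached them.

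Of 100 splits of the tissue libraries into 6 and 6, 2 gave at least the 91 genes called, the real one included. This makes chance unlikely but does not exclude it. The highest other split, with 144, exchanged W11 and W14 with D12 and D14. For the line mice the real count was 0, which each of the 35 splits reaches by construction (highest other 4), so these splits decide nothing. For the difference of effects 3 of 100 splits gave at least 21. The highest other, with 61, kept the tissue groups and regrouped lines only. Marrow labels were regrouped in tissue as well, so the fall in tissue alone could set the real grouping apart. These counts therefore cannot decide whether a difference of effects between lines and tissue arose by chance. These splits regrouped the tissue and the line of 1 mouse independently, so they leave out that pairing. For lines against tissue 1 of 100, the real one, reached 9235, and the highest other gave 3902. Chance is unlikely there, though these splits also left out the pairing.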

How the results depend on the processing

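Runs used alone, run 1 of line G left out, W11 and D12 left out together, the acinar list left out and background subtraction were chosen after seeing the data. Where no cause is named, the cause was not tested. Of 1494 values of named genes under alternatives in tissue, 1308 kept their direction and call, 117 lost the call, 36 gained it and 33 changed sign. In lines against tissue all 528 kept both, and for the difference of effects 127 of 157 did and 30 lost the call. In lines all 451 kept their direction, but no named gene passed in the main fit, so there was no call to lose.

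Against 91 genes in tissue, DESeq2 called 166 (32 higher, 134 lower), no filter 171 (24 and 147, with more genes tested), W11 and D12 left out 187, the Y-linked covariate 56, the acinar covariate 0 (edgeR, 212 at an unadjusted 0.05), and the acinar list left out 44, with fewer acinar genes by construction. Leaving out 1 library gave 62 to 246. Against 15 tissue lists, 1 was called with an estimated correlation and 5 with the acinar covariate, 4 of them among the 15. Against 3 line lists, 0 were called with an estimated correlation, 15 with run 1 only (1 higher, 14 lower, 0 of them among the 3), 13 with run 2 only (2 among the 3), 13 without run 1 of line G (all 3 among them), 5 with voom (2 among the 3), and 2 to 10 with 1 mouse left out. With run 1 only, W12 among the lines stood on run 1 of line G alone, with 66538 counts. Of 25 lists between lines and tissue 0 were called with an estimated correlation.

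Against 21 genes for the difference of effects, DESeq2 called 55, no filter 52, run 2 only 33, run 1 only 0 (edgeR, 562 at an unadjusted 0.05) and background subtraction 0 (572), and leaving out 1 line mouse gave 0 to 12. The replicate block on the mouse, which pairs tissue and line of 1 animal, gave 42, and for lines against tissue 7675 against 9235, 7470 of them shared. It changed no call of a named gene in either comparison, and 26 lists were called between lines and tissue, the main 25 among them. WT and DKOT tissue libraries share only numbers. The 4 pairs correlated at −0.17 to −0.003 in their deviations, and a replicate block on these numbers gave 52 genes (3 higher, 49 lower), with Rc3h2 at −0.12 and Kras at −0.27.

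The acinar score of the DKOT libraries lies below that of all WT libraries, so as a covariate it takes up most of the group difference, and log2 fold changes turned for Mmp8 (−0.29), Wfdc21 (−0.14), Serpini2 (0.052), S100a8 (−0.54), Cxcr2 (−0.27), S100a9 (−0.88), Reg3a (1.02), Reg3g (1.77), Reg3b (1.505), Reg2 (1.17), Reg1 (1.28), Id3 (−0.31), Tnfrsf9 (−0.056), G6pc2 (0.74), Ins2 (1.77), Dmbt1 (0.66), Emcn (−0.66), Herpud1 (0.22), Manf (0.006), Hspa5 (0.083), Rc3h1 (0.18), Tnf (−0.18), Il6 (0.97) and Ptf1a (2.20). With 1 library left out, Rc3h2 ranged from −0.021 to 0.163, Kras from −0.035 to 0.217 and Trbc2 from −0.31 to 0.87. Trbc2 was at −0.41 with voom and −0.35 without W11 and D12. Depth limits tissue W11 and run 1 of line G most.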

Other observations

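All values in this part were chosen after they were seen, apart from the lists. In tissue, 5 more lists were called without a member past the threshold over all genes or when adjusted over the list alone. B and plasma cell genes were lower (median log2 fold change −0.35, camera adjusted p = 0.00313, and adjusted p = 0.601 with an estimated correlation). Targets of TGF-β were higher (0.44, adjusted p = 0.00916, and adjusted p = 0.716 with an estimated correlation), but not without D17 (adjusted p = 0.169). Genes of the epithelial-mesenchymal transition were higher (0.34, adjusted p = 0.0131, and adjusted p = 0.536 with an estimated correlation), but not without W12, D15 or D17 (adjusted p = 0.0509, 0.054 and 0.138). Fibroblast and matrix genes were higher (0.22, adjusted p = 0.0206, and adjusted p = 0.666 with an estimated correlation), but not without W11, W12, W14, D13, D15 or D17 (highest adjusted p = 0.182). Proliferation genes were lower (−0.18, adjusted p = 0.0346, and adjusted p = 0.945 with an estimated correlation), but not without W11, D13, D16 or D17 (highest adjusted p = 0.754). Counting all 25 alternatives, these calls were lost in 0 for B and plasma cells, 3 for TGF-β targets, 5 for the epithelial-mesenchymal transition, 12 for fibroblast and matrix genes and 11 for proliferation. With the acinar covariate the TGF-β, epithelial-mesenchymal and fibroblast lists turned direction (adjusted p = 0.908, 0.997 and 0.0755), as did proliferation with the background subtracted (median 0.15, adjusted p = 0.432) and with a replicate block on shared numbers (median 0.11, adjusted p = 0.273).

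Lines held more transcripts of mitochondrial respiration than tissue, with 15 of 17 members higher, also when adjusted over the list alone (median log2 fold change 0.70, camera adjusted p = 0.000177, and adjusted p = 0.372 with an estimated correlation). Of 20 genes of cholesterol and fatty acid synthesis 15 were higher and 1 lower, also when adjusted over the list alone (median 1.08, camera adjusted p = 0.00116, and adjusted p = 0.372 with an estimated correlation).

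Tissue D12 stood apart from the other 11 tissue libraries, in plain CPM, with 4715 for Cfd and 3058 for Car3, which fat cells express, and 4774 for the lymphoid chemokine Cxcl13, while the epithelial gene Epcam was lowest there (131.3). The 8 lines differed widely in Epcam, from 61.1 plain CPM in line A and 419 in line B, both of mouse D13, to 849 in line E and 1232 in line H. The Y-linked Ddx3y was between 0.368 and 2.48 plain CPM in tissue D13, D14 and D15, all with DKOT marrow. It was between 15.6 and 43.1 in the other 9 tissue libraries, which include all WT libraries. In the lines Xist was at 282, 259 and 265 plain CPM in F, A and B, and between 20.4 and 29.1 in the other 5. Lines A and B came from D13, where tissue Ddx3y was low, but line F came from W11, whose tissue was in the higher range. The background would make up 70.37% and 72.91% of the W11 tissue wells, if as much reached them, so the Y-linked level of W11 tissue is uncertain. Line D had neither Xist (29.1) nor Ddx3y (0.775) above the level of lines without it, and line H held 1.16 of Ddx3y but 52.5 of Eif2s3y.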
